A study of Mus musculus with 10 samples.

How the data were processed

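RNA-seq expression profiles of 10 mouse libraries were used, 2 in each of 5 groups: embryonic stem (ES) cells grown on feeder fibroblasts, splenic B cells, splenic CD4 T cells, T cells cultured under T helper 2 (Th2) conditions for 5 days, and the same kind of culture with the histone deacetylase inhibitor trichostatin A (TSA). Per the labels' protocols, the B and CD4 T cells were sorted to over 98% purity, and 10 nM TSA was added on day 2 of the culture and left for 3 days. Groups and replicate numbers were taken from the sample titles.

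The deposited files give 1 value per transcript row in FPKM, a unit of fragments already divided by transcript length and by library total. Per the submitters' processing notes, Bowtie 0.12.8, TopHat 1.3.2 and Cufflinks 2.0.2 were used with the mm10 build. The settings of these tools, the treatment of reads that match several places, the use of strand and the read numbers are not given in the sources used here. Because FPKM keeps no read counts, the depth of each library is unknown and no counting interval is given. The deposited FPKM values summed to between 405438.5 and 521872.1 per library.

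Each file held 21035 rows, which collapsed to 19025 genes. Of the row accessions, 20482 were found in the RefSeq table of GRCm38.p6, and 553 were not. That table was used to name the 315 rows without a symbol and the 30 rows with a date in place of a symbol. Any of these rows not found there kept its accession as its name. The files were of 2 kinds. Among 1251 symbols with more than 1 row, the rows above 0 were identical for 1214 symbols in the 4 Th2 files and for 6 symbols in the 6 ES, B and CD4 T files. The Th2 files thus repeat 1 value per symbol, while the other files hold a value per transcript. For this reason the value of a gene was the highest of its rows, where the plan had been to sum rows. Sums and means were computed as alternatives. In the 4 Th2 files 20 rows stood at 0 that were above 10 FPKM in all 6 other files, and 12 of these carried date symbols. A value of 0 throughout one kind of file can therefore be a failed match of names, and such genes were given no fold change between Th2 and CD4 T cells.

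The libraries of each group were compared before averaging. Those of the ES, B and CD4 T groups differed by no more than read sampling, as described in the report, and each of these pairs was averaged and counted as 1 sample. The plan had been limma on 10 separate samples. With 7 samples, the comparisons among ES, B and CD4 T cells have 1 sample on each side and no replicate test of their own. For these, genes were taken by a fixed rule of size: a log2 fold change of at least 2 in either direction and at least 5 FPKM in the higher group. Gene lists were described by the percentile of their median among 10000 random lists of the same size, drawn from 20 bins of mean expression. A list outside the central 95% is called outside the random range.

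The Th2 and CD4 T cells, and the treated and untreated Th2 cultures, were compared with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a prior spread that follows mean expression and 7 samples sharing 1 estimate of the spread. This fit has 2 residual degrees of freedom, and the single CD4 T sample is assumed to vary like the Th2 groups. The 12907 genes with an FPKM of 1 or more in at least 2 libraries were tested, two-sided, with Benjamini-Hochberg adjustment, and an adjusted p below 0.05 was a call. Of these genes, 467 were at 0 in all 4 Th2 files and 73 in all 6 others, which left 12367 for Th2 against CD4 T cells. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The labels do not say whether replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

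Before the data were examined, 29 gene lists were fixed: markers of pluripotent, B, T, CD8 and cytotoxic, regulatory T, plasma, myeloid, erythroid and fibroblast cells; Th2, Th1, Th17 and follicular helper, naive and activation genes; cell cycle, Polycomb, Trithorax, histone deacetylase, Hox, developmental factor, reported HDAC inhibitor response, neuronal, germline, imprinted, immediate early, interferon, glycolysis, cholesterol synthesis and ribosome biogenesis genes. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. With an estimated correlation camera rests on the 2 residual degrees of freedom, and it called no list in any comparison. A call lost in it therefore cannot tell correlated genes from too few samples. Named genes are the 10 largest changes in each direction among calls with at least 5 FPKM in the higher group whose libraries do not overlap, up to 4 members per list by size of change, and Pou5f1, Cd3e, Cd4, Gata3, Il4, Ezh2, Men1 and Kmt2a. Some genes that this rule names are not reported here. Small RNAs, numbered gene models, Riken clones, pseudogenes and antigen receptor segments were excluded from the largest changes. In the comparisons among ES, B and CD4 T cells the size rule took the place of the call, and a test on the spread pooled from the Th2 files was run as an alternative chosen after seeing the data. Outside this rule, H2-Aa in CD4 T against B cells, Il5, Il7r, Klf2, Top2a, Txnip and Irf7 in Th2 against CD4 T cells, and Setd1a, Rrp9, Il4ra, Tbx21, Tnf and H1f0 with TSA, were chosen after their values were seen.

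The steps were tested on simulated data. With 200 changed genes simulated in 12907, limma called 30 of 100 genes changed by log2 1 and 80 of 100 changed by log2 2 between treated and untreated Th2 cultures, with 4 false calls among 114 calls. For Th2 against CD4 T cells, with 12367 genes, it called 5 of 100 at log2 1 and 62 of 100 at log2 2, with 11 false calls among 78 calls. Far fewer genes were changed in these simulations than were called in the data, so their rates need not hold there. For the list percentiles, simulated on CD4 T against B cells with 12907 genes, 7 of 100 lists without a shift and 100 of 100 lists shifted by log2 1 lay outside the random range. Alternatives covered the pseudocount, the filter, scaling, the model of the spread, a replicate term, genes with several rows and each library left out. Row sums and separate libraries, which had been the plan, were also run as alternatives. Row means and further ways to count libraries were chosen after seeing the data. Positions are from RefSeq on GRCm38.p6, which shares its coordinates with mm10.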

Results

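Gene expression was measured by RNA-seq in mouse ES cells, B cells and CD4 T cells, and in Th2 cultures with or without TSA, to compare their expression profiles in a series on Polycomb and Trithorax complexes. Each group had 2 libraries. Between 9652 and 11456 genes per library had an FPKM of 1 or more. Ribosomal protein genes took 8.44% to 12% of the summed FPKM in the ES, B and CD4 T libraries, 16.9% and 18.5% in the untreated Th2 libraries and 21.8% and 22.2% in the TSA-treated ones.

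The 2 libraries of ES, of B and of CD4 T cells differed by no more than the noise of sampling reads. The SD of the log2 ratio between them was 0.039, 0.042 and 0.043, against 0.30 for the untreated and 0.308 for the treated Th2 libraries. If sampling were the only source of spread, the depth computed from genes of different abundance would be constant. It varied by 1.52-fold in ES, 1.09-fold in B and 1.15-fold in CD4 T cells, but by 27.9-fold and 28.9-fold in the Th2 groups. Each of the first 3 pairs was therefore counted as 1 sample, and only the Th2 groups have n = 2.

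**Figure D1:**
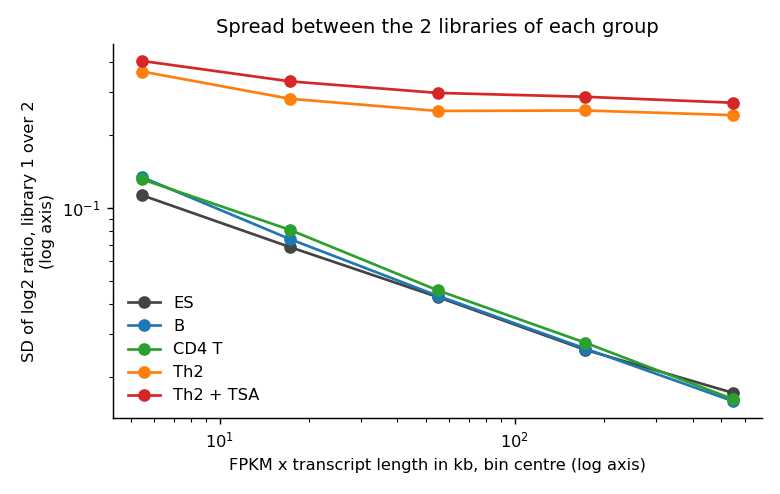
SD of the log2 ratio between the 2 libraries of each group (log axis), against FPKM times transcript length in kb (log axis), with 1 point per bin of genes. The ES, B and CD4 T lines fall steadily with abundance, while the Th2 lines level off above 0.24.

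CD4 T cells were compared with ES cells to see which genes separate a T lymphocyte from a pluripotent cell. T cell list genes stood higher in CD4 T cells, and pluripotency genes in ES cells. Cd3g, a chain of the CD3 signalling complex, was at 393 FPKM against 0.12 (log2 fold change 8.47), and the co-receptor gene Cd4 was at 299 against 0.32. Pou5f1, the gene of the pluripotency factor Oct4, was at 0.86 FPKM in CD4 T cells and 620.1 in ES cells, and Dppa5a at 0.10 and 1041. All 25 T cell list genes passed the size rule upward and all 24 measured pluripotency genes passed it downward, with list medians of 6.06 and -5.92. With camera on a spread pooled from the Th2 files and an estimated correlation, none of the 29 lists was called in this comparison (lowest adjusted p = 0.22).

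By the size rule 1389 genes were higher and 1531 lower in CD4 T than in ES cells, among 12907. The largest increases included the lymphocyte GTPase family genes Gimap4 (1140.1 against 0.63 FPKM), Gimap3 and Gimap6, the membrane protein genes Ms4a4b and Ms4a6b, Ptprc, which encodes the leukocyte antigen CD45, and Cd52, Sp100 and H2-Aa. The largest decreases included the metallothionein gene Mt2 (0.62 against 995.1), Spp1, Trh, Igfbp2, L1td1, Bgn and Zfp57. Quiescence genes stood high in CD4 T cells, with 17 of 20 passing the rule and a list median of 3.46, among them Il7r (223 against 0.32). Interferon response genes were higher for 20 of 23 members, among them Irf7 (81.7 against 0.45).

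In the cell cycle list 21 of 27 genes passed the rule downward in CD4 T cells, including Ccnb1 (2.16 against 58.6 FPKM) and Cdc20 (7.42 against 146.6). In the glycolysis list 13 of 18 did, including the hexokinase gene Hk2 (2.36 against 75.2) and the glucose transporter gene Slc2a1 (18.9 against 361), and in the ribosome biogenesis list 8 of 21, including Npm1 (200.3 against 1566). The imprinted genes Peg10 (0.06 against 119) and Igf2 (0.18 against 96.0) were among 11 of 17 imprinted genes lower in CD4 T cells. Lists of developmental factors, neuronal genes, germline genes and reported HDAC inhibitor response genes also lay below the random range, with medians of -1.65, -2.13, -2.18 and -1.24, of which the first was -0.90 after quantile normalization. Their leading members were Olig1, listed at 0 in CD4 T cells and at 18.8 in ES cells, Stmn2 (0.07 against 106), Tex19.1, listed at 0 against 38.9, and Mt1 (3.67 against 809.9).

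Chromatin regulators were divided. Of 32 Polycomb genes, 4 passed the rule upward and 3 downward, with a median of -0.97 at percentile 0.16. Phf1 (80.8 against 5.68 FPKM) was higher in CD4 T cells, and Pcgf2 (2.26 against 37.2) and Phc1 (11.2 against 120.02) lower. Ezh2, the H3K27 methyltransferase gene, was at 28.4 in CD4 T and 83.1 in ES cells. The Trithorax list lay within the random range, at percentile 38.2. Within it Kmt2a was higher in CD4 T cells (51.7 against 9.90) and Ash2l lower (17.7 against 96.0), while Men1 was at 18.9 and 22.8. Histone deacetylase genes also lay within the range, at percentile 88.1, with Hdac7 at 68.9 against 5.10.

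Markers of other cells were present in both libraries. The fibroblast genes Col1a1 (147 FPKM) and Acta2 (193) stood high in the ES library, whose cells grew on feeder fibroblasts, and 19 of 20 fibroblast genes passed the rule downward in CD4 T cells. The CD4 T library held B list genes, with 22 of 25 above ES cells, including Cd74 (1237 against 4.26), and myeloid genes, with 12 of 18 above ES cells, including Csf1r (54.3 against 0.89). The CD8 and cytotoxic, regulatory T, Th1, Th2, Th17 and follicular helper, activation and immediate early lists lay above the random range, with medians of 2.86, 2.94, 3.32, 1.60, 1.69, 3.53 and 1.56. Plasma cell and erythroid genes lay within it, with medians of -0.15 (-0.09 after median-ratio scaling) and 0.84. The Hox list had a median of -1.19 at percentile 2.45 (-0.44 after quantile normalization), with no member at 5 FPKM, and the cholesterol list one of -1.03. With 1 sample on each side, none of these differences has a replicate check.

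B cells were compared with ES cells in the same way. B list genes stood higher in B cells, and pluripotency genes in ES cells. Cd74, the class II invariant chain gene, was at 6682 FPKM in B cells and 4.26 in ES cells, and the B cell receptor gene Cd79b at 1108 and 0.86 (log2 fold change 9.22). All 25 B list genes passed the size rule upward (median 8.12), and all 24 pluripotency genes passed it downward (median -5.92), with Pou5f1 at 1.36 against 620.1. No list was called by camera on the pooled spread with an estimated correlation (lowest adjusted p = 0.34).

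By the size rule 1220 genes were higher and 1727 lower in B than in ES cells. The largest increases included Cd74, H2-Aa, H2-Ab1, H2-Eb1 and H2-Ob of class II, and Cd79b, Ms4a1, Faim3 and Ly6d. The largest decreases included Mt2, Dppa5a, Spp1, Tdgf1, Mt1, Utf1, Pou5f1, Trh and Bgn, with Tdgf1 at 0.06 against 353 and Utf1 at 0.18 against 327. Cell cycle genes were lower for 22 of 27 members, among them Ccnb1 (1.77 against 58.6), and glycolysis genes for 14 of 18, among them Slc16a3 (0.62 against 60.7). Of 32 Polycomb genes 2 were higher and 5 lower, with Pcgf2 at 0.32 against 37.2, Ezh2 at 24.2 and a list median of -0.90 at percentile 1.58. Kmt2a was at 50.6 in B cells, and the Trithorax list was at percentile 37.2.

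In the other lists of B against ES cells, interferon genes were higher for 18 of 23 members, including Irf7 (39.9 against 0.45), and quiescence genes for 11 of 20, including Ccr7 (104 against 0.46). The cytotoxic, Th1, Th17 and follicular helper, and activation lists had medians of 2.68, 2.19, 0.86 and 0.47 above the random range, with Gzma at 46.8 in B cells and listed at 0 in ES cells, and Cxcr5 at 164 against 0.10. The T cell list also lay above the range, with a median of 0.96, although 22 of 25 members were short of the size rule, with Cd3e at 2.02. Fibroblast genes were lower for 20 of 20 members, and myeloid genes higher for 7 of 18, led by Cybb (90.3 against 0.51) and Spi1, which B cells also express. Ribosome biogenesis, cholesterol, imprinted, neuronal, germline, developmental factor and HDAC inhibitor response lists lay below the range, with medians of -1.79, -1.21, -3.55, -2.20, -2.15, -1.60 and -2.32. Regulatory T, plasma, erythroid, Th2, Hox, histone deacetylase and immediate early lists lay within it, at percentiles 62.0, 66.5, 84.8, 80.6, 8.45, 90.6 and 97.4. After quantile normalization the medians of the Th17 and follicular helper and the developmental factor lists were 1.47 and -0.80, and the median of all genes moved by 0.23 on the log2 scale, from -0.30 to -0.07.

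CD4 T cells were compared with B cells to separate the lymphocyte lineages. T cell list genes were higher in CD4 T cells and B list genes in B cells. Cd3e was at 244 FPKM in CD4 T and 2.02 in B cells (log2 fold change 6.35), and Cd40lg, the ligand through which T cells help B cells, at 77.8 and 0.14. The B lineage factor gene Pax5 was at 20.9 and 442. T cell genes passed the size rule upward for 24 of 25 members (median 5.11) and B list genes downward for 23 of 25 (median -3.79). Of all lists 16 lay outside the random range, while camera, a different test, called at the preset correlation 7 with separate libraries and 8 with the pooled spread, and with an estimated correlation none (lowest adjusted p = 0.424).

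By the size rule 331 genes were higher and 220 lower in CD4 T than in B cells. The largest increases were Igfbp4 (167 against 0.42 FPKM), Als2cl, Cd3e, Cd6, Cd3g, Cd40lg, Cd3d, Thy1, Lat and Tcf7, and the largest decreases included Fcer2a, Pax5, Faim3, Scd1, Cd79b, Chst3, Cd79a, Ms4a1 and Cr2. Regulatory T cell genes were higher for 9 of 11 members, including Foxp3 (30.7 against 2.16) and Ctla4 (52.1 against 1.21), and activation receptor genes for 9 of 15, including Icos (31.4 against 0.44). Gata3 was at 20.1 and 0.51, Il4 at 5.02 and 0.06, and the Th2 list median was 0.94. Quiescence genes were higher for 9 of 20 members, led by Igfbp4 and Tcf7 (557 against 7.99).

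Between CD4 T and B cells none of 32 Polycomb, 17 Trithorax or 27 cell cycle genes passed the size rule, and their medians were 0.11, 0.09 and 0.19, within the random range. After median-ratio scaling the first 2 medians were -0.04 and -0.06, and after quantile normalization the cell cycle median was -0.02. Ezh2 was at 28.4 and 24.2 FPKM, Kmt2a at 51.7 and 50.6, and Men1 at 18.9 and 19.9. Among histone deacetylases Hdac9 stood higher in B cells (17.3 against 2.95), and the list median was -0.10, or -0.24 after median-ratio scaling. Myeloid genes had a median of 1.33 above the random range, with Lyz2 at 93.2 in CD4 T and 16.7 in B cells and C1qa at 73.4 and 21.8. The cytotoxic, Th1, Th17 and follicular helper, interferon, immediate early, glycolysis and cholesterol lists had medians of 0.58, 0.78, 0.53, 0.81, 0.77, 0.33 and 0.40, all above the range, and plasma genes one of -1.64 below it, with Mzb1 at 18.8 and 168. Of these the cytotoxic and the Th17 and follicular helper medians were 0.35 and 0.27 after quantile normalization, and the glycolysis and cholesterol medians 0.18 and 0.26 after median-ratio scaling. Gzma (3.36 against 46.8) and Ncr1 (1.07 against 14.7) were higher in the B library. Pluripotency genes had a median of -0.01 (-0.04 after quantile normalization), below a random range that began at 0. Erythroid, fibroblast, HDAC inhibitor response, neuronal, germline, imprinted, Hox, developmental factor and ribosome biogenesis genes had medians between -0.02 and 0.70 within the range. The highest, of erythroid genes, was 0.33 after quantile normalization, and the lowest, of ribosome biogenesis genes, -0.18 after median-ratio scaling. With 1 sample on each side, these differences have no replicate check.

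B list genes stood in the CD4 T library at similar shares of their level in the B library. Over 20 B list genes outside MHC class II the median share was 6.07%, with quartiles of 5.81% and 8.45%. Over 5 class II pathway genes the median was 24.9%, with H2-Aa at 598 against 2402 FPKM.

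**Figure D2:**
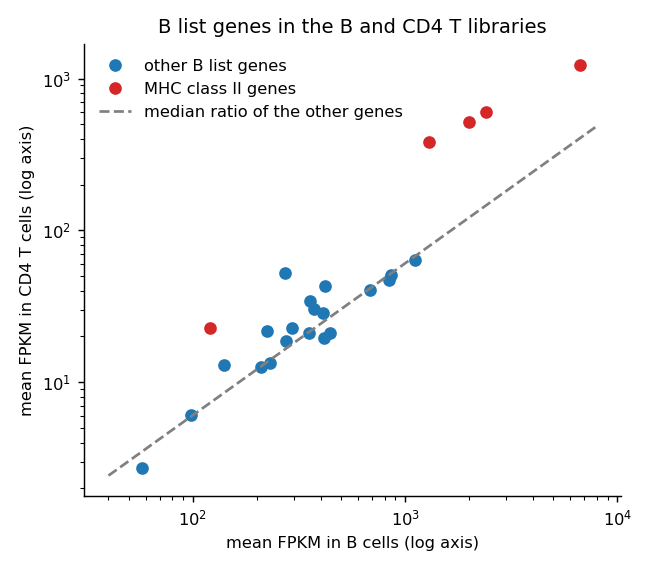
Mean FPKM of 25 B list genes in CD4 T cells (log axis) against that in B cells (log axis), with MHC class II genes in red and the other genes in blue; the dashed line marks the median share of the other genes, 6.07%. The red points lie above the line.

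**Figure D3:**
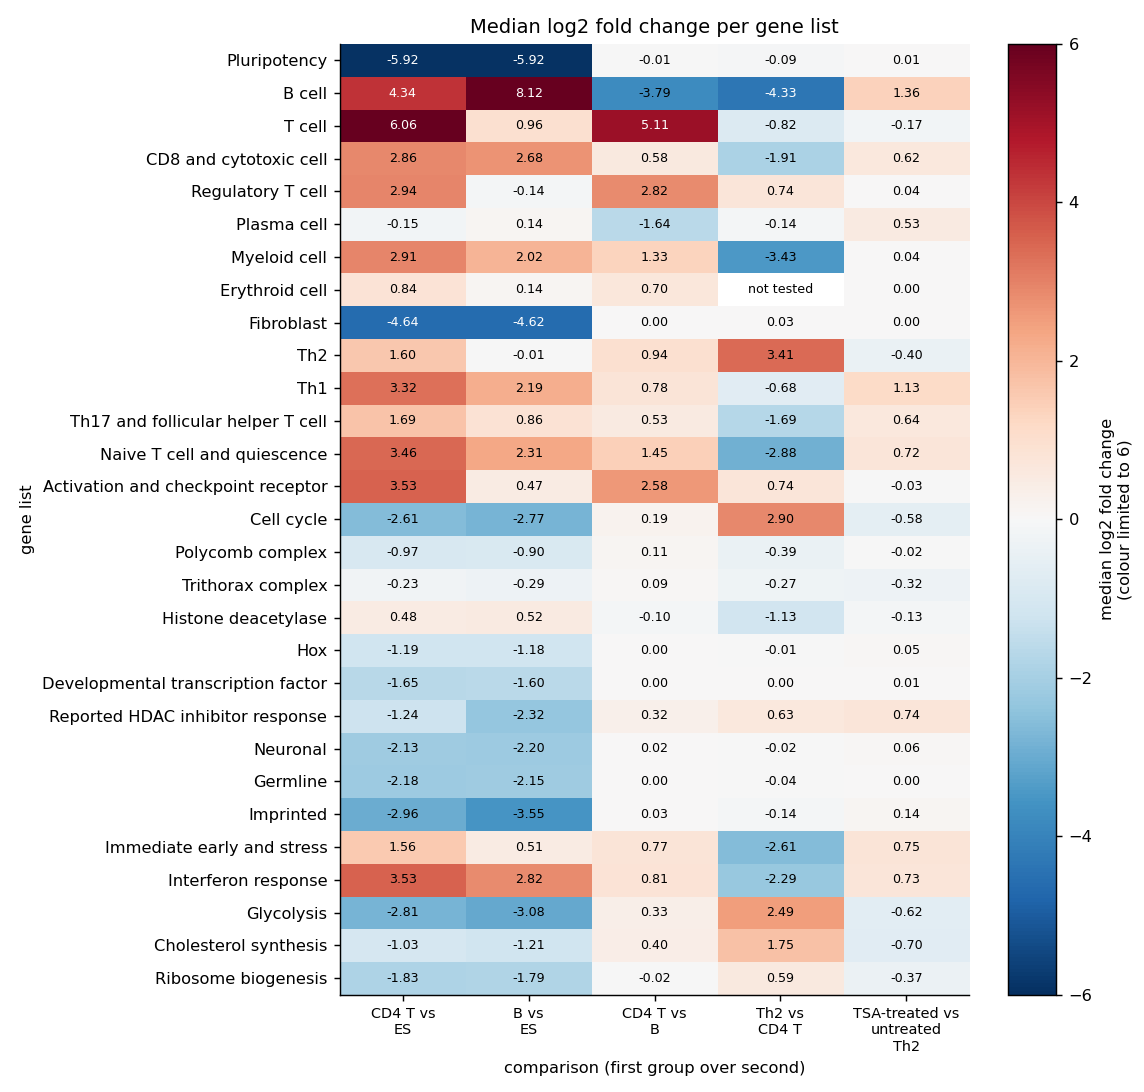
Median log2 fold change of each gene list (rows) in each comparison (columns, first group over second), as number and colour. Pluripotency genes stand at -5.92 in both comparisons with ES cells, and cell cycle genes at 2.90 in Th2 against CD4 T cells.

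Th2 cultures were compared with CD4 T cells to follow 5 days of activation and Th2 differentiation with IL-2 and IL-4. Genes of the Th2, cell cycle and glycolysis lists rose in 14 of 17, 27 of 27 and 14 of 18 members, and quiescence genes of naive T cells fell in 18 of 20. With an estimated correlation these list calls were lost (camera adjusted p = 0.63, 0.702, 0.794 and 0.63). That test, on 2 residual degrees of freedom, called no list in any comparison. Il4 was at 85.7 ± 14.5 FPKM (SD, n = 2) in Th2 cultures and 5.02 in CD4 T cells, Gata3, the Th2 master regulator gene, at 89.2 ± 12.6 and 20.1, and the granzyme gene Gzmb at 1893 ± 235 and 2.51 (log2 fold change 9.07, SE 0.29, limma adjusted p = 0.00134). Tcf7, a factor of naive T cells, fell from 557 to 15.6 ± 1.31, and Klf2 and Il7r fell with it among quiescence genes.

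With limma, 2086 genes were higher and 4709 lower in Th2 cultures among 12367 tested. The median of all genes was -0.28, and it was 0.02 after quantile normalization, where 3442 genes were higher and 3405 lower, and -0.03 after median-ratio scaling, with 2887 and 3387. The largest increases were Gzmb, the steroid synthesis gene Cyp11a1 (470 ± 90.8 FPKM against 0.15), Il24, Gzma (662 ± 457 against 3.36), Lif, Tnfrsf8, Nfil3, Cdkn1a, Fam229b and Tuba1b. The largest decreases were Patl2, H2-Aa, Raet1c, Raet1b, Raet1a, Tyrobp, H2-Eb1, Lyz2, Dtx1 and Dapl1. Among these, H2-Aa and H2-Eb1 are B list genes and Lyz2 is a myeloid list gene, and the CD4 T library held transcripts of both lists. Tyrobp and Dtx1 stood at 86.7 and 75.7 FPKM in the B library, so their falls may also reflect fewer other cells in the cultures. Raet1a, Raet1b and Raet1c are near-identical paralogs, of which Raet1a and Raet1c were listed at 0 in both untreated Th2 libraries, Tuba1b has near-identical tubulin copies, and Patl2, at 632 against 0.12 ± 0.12, spans B2m in the annotation, so their values are uncertain.

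The list of Th2 genes rose in 14 of 17 members and fell in 1 (14 and 1 when adjusted over the list alone), with a median of 3.41 and a camera adjusted p = 1.11e-08. Il10 rose from 1.19 to 136 ± 32.5 FPKM, Il13 from 0.16 to 27.3 ± 6.77, Il5 from 0.01 to 22.9 ± 0.19 and Nfil3 from 2.09 to 210 ± 31.1. Cell cycle genes rose in 27 of 27 members (27 adjusted over the list alone; median 2.90, camera adjusted p = 3.23e-17), with Ccnb1 at 79.1 ± 9.24 against 2.16 and Top2a at 263 ± 54.8 against 21.5. Glycolysis genes rose in 14 of 18 (15 adjusted over the list alone; camera adjusted p = 1.42e-08), led by Pgk1, Pgam1 and Tpi1, which have processed pseudogenes and whose values may be split between copies. Cholesterol synthesis genes rose in 18 of 20 (19 adjusted over the list alone; camera adjusted p = 2.23e-10), with Idi1 at 57.8 ± 1.29 against 1.02, and ribosome biogenesis genes in 6 of 21 (4 adjusted over the list alone; camera adjusted p = 4.06e-05), with Npm1 at 526 ± 44.7 against 200.3. The reported HDAC inhibitor response list was called upward (6 up and 3 down of 14, also when adjusted over the list alone; camera adjusted p = 0.0477), with Cdkn1a at 140 ± 40.9 against 1.08 and Txnip lower, at 66.3 ± 1.71 against 514. With an estimated correlation none of these calls held, and the adjusted p was 0.63 for Th2, 0.702 for cell cycle and cholesterol, and 0.794 for glycolysis, ribosome biogenesis and HDAC inhibitor response genes. The last 2 lists were not called by fry either, which tests a list against no change (adjusted p = 0.151 for each).

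Quiescence genes fell in 18 of 20 members and rose in 1 (18 and 1 adjusted over the list alone; median -2.88, camera adjusted p = 0.000335, or adjusted p = 0.63 with an estimated correlation), with Il6ra falling from 87.9 to 1.96 ± 0.13 FPKM and Actn1 from 130.4 to 4.34 ± 0.01. Interferon response genes fell in 19 of 23 (19 adjusted over the list alone; camera adjusted p = 3.27e-05, or adjusted p = 0.794 with an estimated correlation), with Irf7 at 8.04 ± 1.03 against 81.7. Th17 and follicular helper genes fell in 7 of 9 (7 adjusted over the list alone; camera adjusted p = 0.0141, or adjusted p = 0.794 with an estimated correlation), with Bcl6 at 0.22 ± 0.01 against 13.1 and Cxcr5 at 0.30 ± 0.13 against 15.6. B list genes fell in 23 of 25 (24 adjusted over the list alone; camera adjusted p = 1.34e-06, or adjusted p = 0.794 with an estimated correlation) and myeloid genes in 15 of 15 (15 adjusted over the list alone; camera adjusted p = 3.5e-07, or adjusted p = 0.63 with an estimated correlation), with Lyz2 at 0.08 ± 0.05 against 93.2. The CD4 T library held B list and myeloid transcripts, and Cxcr5 stood at 164 FPKM in the B library. Falls of such genes cannot be told apart from fewer B and myeloid cells in the cultures. Immediate early genes had 13 of 19 members lower and 2 higher (13 and 2 adjusted over the list alone), with Egr1 at 1.92 ± 0.94 against 42.1, and the list was short of a call (camera adjusted p = 0.0555).

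The Polycomb list had 8 members higher and 11 lower of 32 (9 and 13 adjusted over the list alone; camera adjusted p = 0.683), and its median of -0.39 became -0.02 after median-ratio scaling. Ezh2 rose from 28.4 to 122 ± 17.9 FPKM (log2 fold change 2.06, SE 0.22, limma adjusted p = 0.00861) and Phf19 from 2.44 to 11.5 ± 0.24, while Phf1 fell from 80.8 to 11.4 ± 2.20 and Cbx7 from 92.4 to 15.3 ± 1.27. Of 17 Trithorax genes 1 rose and 7 fell (1 and 6 adjusted over the list alone; camera adjusted p = 0.918), among them Kmt2a, from 51.7 to 11.8 ± 3.10, and Kmt2c, from 39.5 to 5.08 ± 1.01. Men1 was at 33.8 ± 6.00 against 18.9. Of 11 histone deacetylase genes 2 rose and 4 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.715), with Hdac8 at 5.17 ± 0.07 against 26.6. Fry called the histone deacetylase and Polycomb lists (fry adjusted p = 0.00303 and 0.0169) but not the Trithorax list (fry adjusted p = 0.0724).

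The T cell list had 4 members higher and 14 lower of 25 (5 and 15 adjusted over the list alone; camera adjusted p = 0.314), with Icos at 238 ± 34.0 against 31.4, Cd3e at 123 ± 14.6 against 244 and Cd4 at 133 ± 2.59 against 299. Regulatory T cell genes were divided (4 up and 5 down of 11, also when adjusted over the list alone; camera adjusted p = 0.715), with Il2ra rising from 20.0 to 682 ± 50.8 and Foxp3 falling from 30.7 to 0.84 ± 0.40. The fall of Foxp3 cannot be told apart from fewer regulatory T cells in the cultures. The activation (8 up and 4 down of 15), Th1 (2 and 6 of 16) and cytotoxic (3 and 12 of 18) lists had the same counts adjusted over the list alone and camera adjusted p = 0.0709, 0.892 and 0.118, and the plasma cell list had 3 up and none down of 7 (2 adjusted over the list alone; camera adjusted p = 0.128). Camera, which compares a list with all other genes, pointed upward for the Polycomb, Th1 and plasma lists, whose medians of -0.39, -0.68 and -0.14 were below 0, and for the neuronal and germline lists (-0.02 and -0.04). After median-ratio scaling the Th1 median was -0.32, and after quantile normalization the neuronal and germline medians were 0.10 and 0.07. The regulatory T list had a median of 0.74 (1.12 after median-ratio scaling) and a mean of -0.34. The Trithorax median of -0.27 became 0.09 and the plasma median 0.12 after median-ratio scaling. The pluripotency (1 up and 5 down of 16), fibroblast (2 and 3 of 15), Hox (0 and 3 of 11), developmental factor (0 and 1 of 11), neuronal (2 and 3 of 20), germline (2 and 3 of 9) and imprinted lists (1 and 7 of 17) had the same counts adjusted over the list alone and were not called, with camera adjusted p = 0.715, 0.351, 0.892, 0.588, 0.584, 0.966 and 0.933, and erythroid genes had under 5 tested members. Th2 and CD4 T files were made in different ways, so the file kind and the group cannot be told apart in this comparison. Without a Th2 library the count of calls was 3443 or 3188 in place of 6795.

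TSA-treated and untreated Th2 cultures were compared to find the genes that respond when histone deacetylases are inhibited. With TSA, interferon response genes rose in 9 of 23 members and Th1 genes in 5 of 16, and cholesterol synthesis genes fell in 7 of 20. With an estimated correlation, on 2 residual degrees of freedom, these list calls were lost (camera adjusted p = 0.755 for each), and no other list was called. None of the 12 lists called by camera was called by fry, which tests a list against no change (lowest adjusted p = 0.063). Gbp2, an interferon-inducible GTPase gene, rose from 26.5 ± 0.30 to 480.1 ± 160 FPKM (SD, n = 2 in each group), and Uchl1, a neuronal deubiquitinase gene, from 1.42 ± 0.26 to 58.9 ± 22.5 (log2 fold change 4.58, SE 0.34, limma adjusted p = 0.0293). Il5 fell from 22.9 ± 0.19 to 3.00 ± 1.3 and Gata3 from 89.2 ± 12.6 to 49.1 ± 0.16. Il4 was at 85.7 ± 14.5 and 66.8 ± 0.72 (limma adjusted p = 0.216).

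With limma 1195 genes rose and 534 fell among 12907, of which 100 rose and 16 fell by at least log2 2 with 5 FPKM or more. The largest increases were Uchl1, Gstt1, Gbp2, Mt3, Bex1, Klrk1, Mnda, Itm2a, Syp and Rundc3a. Gstt1, a glutathione transferase gene, went from 0.74 ± 0.35 to 30.1 ± 3.10 FPKM, Itm2a from 61.5 ± 3.50 to 607 ± 185, and Syp, the gene of synaptophysin, from 0.44 ± 0.15 to 12.7 ± 4.91. The largest decreases were Emilin2 (61.3 ± 16.4 to 3.14 ± 0.76), Penk (80.8 ± 12.2 to 5.54 ± 0.86), Sval1, the fatty acid desaturase gene Fads2, Rnf128, Il5, Trat1, Slfn2, Gp49a and Emr1. Mnda and Gp49a belong to families with near-identical members, and their values are uncertain. The split of 1195 up and 534 down became 1110 and 745 after median-ratio scaling and 1125 and 1027 after quantile normalization. Limma called 771 genes with no filter (570 up and 201 down) and 2833 with the filter on the 4 Th2 files (1716 and 1117), which was chosen after seeing the data.

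Of the 12907 genes, 467 were at 0 in all 4 Th2 files and could show no change. Without them, a choice made after seeing the data, 1795 genes rose and 935 fell among 12440. Such genes were 8 of 24 pluripotency, 5 of 20 fibroblast, 3 of 14 Hox, 8 of 19 developmental factor, 5 of 14 germline, 3 of 18 myeloid, 1 of 21 neuronal and 1 of 19 cytotoxic genes. Without them the first 5 of these lists had 16, 15, 11, 11 and 9 members and were still not called (camera adjusted p = 0.366, 0.528, 0.0776, 0.336 and 0.366), and the erythroid list had under 5 members left. The cytotoxic, quiescence, and Th17 and follicular helper lists gained calls (camera adjusted p = 0.0182, 0.0399 and 0.0399), and these were lost with an estimated correlation (adjusted p = 0.69 for each).

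**Figure D4:**
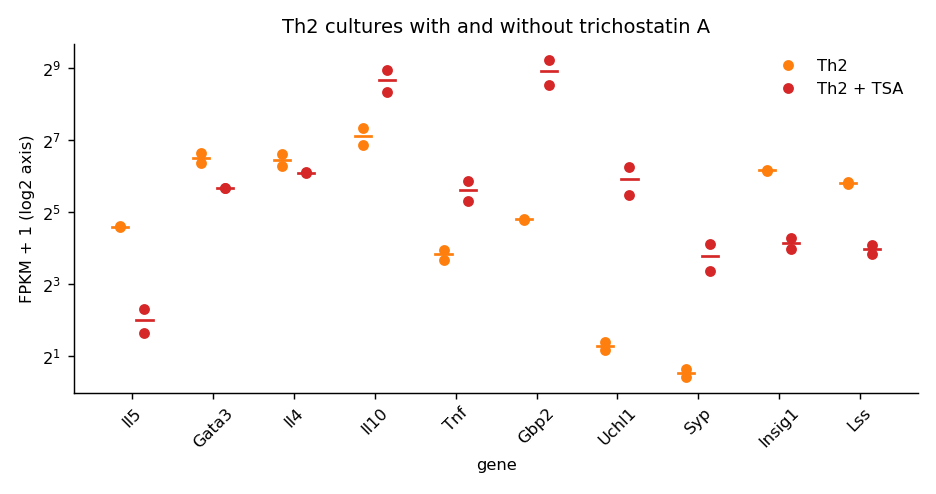
FPKM + 1 on a log2 axis for 10 genes in untreated (orange) and TSA-treated (red) Th2 libraries, with 1 point per library and a bar at the mean of 2. Il5, Insig1 and Lss stand lower, and Gbp2 and Uchl1 higher, in both treated libraries.

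Cholesterol synthesis genes fell in 7 of 20 members and rose in none (16 fell when adjusted over the list alone; median -0.70, camera adjusted p = 5.68e-08). Insig1 fell from 70.1 ± 0.81 to 16.3 ± 2.71 FPKM, and Lss, the lanosterol synthase gene, from 54.6 ± 1.27 to 14.6 ± 1.94. Cell cycle genes were called downward (median -0.58, camera adjusted p = 7.76e-07) with 2 of 27 members past the test over all genes and 15 lower and 1 higher adjusted over the list alone. Cdc20 was at 67.3 ± 3.81 and 31.2 ± 8.46. Glycolysis (camera adjusted p = 0.00377), Trithorax (0.00838) and ribosome biogenesis genes (0.0117) were also called downward, each with 1 member past the test, Tpi1 (599 ± 156 to 207 ± 15.0), Setd1a (20.6 ± 0.37 to 14.4 ± 0.35) and Rrp9, and none adjusted over the list alone. Each of these 5 calls was lost with an estimated correlation (adjusted p = 0.755).

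The Th2 list was called downward (camera adjusted p = 0.0165, or adjusted p = 0.755 with an estimated correlation), with 5 of 17 members falling and 1 rising (6 and 2 adjusted over the list alone). Il5, Ccr4 (85.5 ± 13.8 to 23.9 ± 6.20 FPKM), Il4ra and Gata3 fell, and Il10 was at 136 ± 32.5 and 401 ± 120.1 (limma adjusted p = 0.0718). Th1 genes were called upward (camera adjusted p = 0.0165, or adjusted p = 0.755 with an estimated correlation) with 5 of 16 members rising (7 adjusted over the list alone), among them Tbx21, the T-bet gene (7.44 ± 0.52 to 22.9 ± 0.71), Il12rb2 (15.3 ± 4.48 to 72.4 ± 13.4) and Tnf (13.1 ± 1.91 to 47.4 ± 12.7). T cell genes were called downward (4 down and 1 up of 25, 5 and 1 adjusted over the list alone; camera adjusted p = 0.0416, or adjusted p = 0.755 with an estimated correlation), with Trat1 at 92.4 ± 26.8 and 14.5 ± 5.14, Lat at 289 ± 7.93 and 169 ± 8.90 and Cd28 rising from 54.0 ± 9.44 to 132 ± 9.38. Cd3e was at 123 ± 14.6 and 96.1 ± 21.2, and Cd4 at 133 ± 2.59 and 173 ± 15.6. With a replicate term the Th2 and T cell lists lost their calls (camera adjusted p = 0.0501 for each).

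Interferon response genes were called upward (9 of 23 rose, 10 adjusted over the list alone; median 0.73, or 0.42 after quantile normalization; camera adjusted p = 0.0133, or adjusted p = 0.755 with an estimated correlation). Besides Gbp2 they included Zbp1 (38.3 ± 0.45 to 226 ± 49.3 FPKM) and Mx1 (1.64 ± 0.40 to 18.5 ± 3.78). Immediate early genes (4 of 19 rose, 6 up and 1 down adjusted over the list alone) and the reported HDAC inhibitor response genes (2 up and 1 down of 14, 4 and 1 adjusted over the list alone) were both called upward with camera adjusted p = 0.0416, or adjusted p = 0.755 with an estimated correlation. With a replicate term the interferon and immediate early lists lost their calls (camera adjusted p = 0.0501 and 0.141). Gsn rose from 45.1 ± 9.44 to 126 ± 11.9 and Atf3 from 10.3 ± 1.60 to 27.2 ± 1.56, while H1f0 fell from 113 ± 7.91 to 58.4 ± 5.63. B list genes were called upward (3 of 25 rose, 10 adjusted over the list alone; median 1.36, camera adjusted p = 5.79e-05, or adjusted p = 0.755 with an estimated correlation), with H2-Aa at 2.70 ± 1.5 and 36.5 ± 26.7 (limma adjusted p = 0.0808).

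Of 32 Polycomb genes 1 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.629). Rybp rose from 6.38 ± 0.45 to 23.3 ± 0.59 FPKM (log2 fold change 1.72, SE 0.10, limma adjusted p = 0.0258), and Phf19 fell from 11.5 ± 0.24 to 2.42 ± 0.33 (log2 fold change -1.88, SE 0.11, limma adjusted p = 0.0273). Ezh2 was at 122 ± 17.9 and 150 ± 23.5, Kmt2a at 11.8 ± 3.10 and 17.6 ± 3.08, and Men1 at 33.8 ± 6.00 and 26.8 ± 3.57, none past the test. Of 11 histone deacetylase genes only Hdac1 rose (78.0 ± 2.38 to 111 ± 3.95; 2 up and 2 down adjusted over the list alone; camera adjusted p = 0.897).

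Quiescence genes were divided, with 5 of 20 rising and 3 falling (9 and 3 adjusted over the list alone; camera adjusted p = 0.0779), with Igfbp4 at 327 ± 4.93 and 82.6 ± 5.01 FPKM. The neuronal list had 3 of 21 members rising (3 adjusted over the list alone) and camera adjusted p = 0.0831. The cytotoxic list had 4 of 19 members rising (5 up and 1 down adjusted over the list alone; camera adjusted p = 0.0529), among them Klrk1 (0.18 ± 0.05 to 12.9 ± 3.91) and Nkg7. The Th17 and follicular helper list had 2 of 9 rising (5 adjusted over the list alone; camera adjusted p = 0.0715), with Il21 at 0.39 ± 0.23 and 5.20 ± 2.23. Regulatory T genes had 3 of 11 rising (3 up and 3 down adjusted over the list alone; camera adjusted p = 0.942), with Nrp1 at 0.32 ± 0.16 and 9.59 ± 3.01, and of 15 activation genes only Havcr2 rose (1 adjusted over the list alone; camera adjusted p = 0.826). The regulatory T median of 0.04 became -0.34 after quantile normalization, and the activation list had a median of -0.03 (-0.05 after median-ratio scaling) and a mean of 0.20. Pluripotency, plasma, myeloid, erythroid, fibroblast, Hox, developmental factor, germline and imprinted lists were not called (camera adjusted p = 0.629, 0.629, 0.669, 0.867, 0.658, 0.0934, 0.493, 0.629 and 0.148). Of their members, 1 of 24 pluripotency genes rose (0 adjusted over the list alone), 1 of 17 imprinted genes rose and 1 fell (5 and 1 adjusted over the list alone), and the others had the same counts adjusted over the list alone: 1 up and 1 down of 18 myeloid and of 14 germline genes, 2 down of 20 fibroblast, 1 up of 19 developmental factor, and 0 of 7 plasma, 6 erythroid and 14 Hox genes. Pou5f1 was listed at 0 in untreated cultures and at 1.31 ± 0.60 in treated ones. With 2 libraries per group the calls rest on each library. Limma called no gene when either untreated library was left out (2743 or 2677 at an unadjusted p under 0.05), 273 without the first and 10 without the second treated library.

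Genes restricted to ES, B or CD4 T cells were followed in the TSA comparison, using log2 fold changes of at least 2 over both other groups. The ES-restricted list includes fibroblast genes such as Col1a1, since the ES cells grew on feeder fibroblasts. The 193 B-restricted genes had a median log2 fold change of 0.36 with TSA, and 25 rose and 3 fell (camera adjusted p = 9.34e-06, or adjusted p = 0.406 with an estimated correlation). The 1592 ES-restricted genes had a median of 0.02, with 207 rising and 42 falling (camera adjusted p = 0.163), and the 223 CD4 T-restricted genes 0.08, with 28 rising and 18 falling (camera adjusted p = 0.476). Of these lists 13.0%, 13.0% and 12.6% of B-restricted, ES-restricted and CD4 T-restricted genes rose, against 9.30% of all genes. Of the ES-restricted genes 174 were at 0 in all 4 Th2 files, and of the B-restricted and CD4 T-restricted genes 15 and 5. Without these genes the medians were 0.46 for B-restricted, 0.05 for ES-restricted and 0.11 for CD4 T-restricted genes, of which 32.0%, 19.4% and 20.6% rose, against 14.4% of all genes (camera adjusted p = 5.73e-07, 0.119 and 0.456, or adjusted p = 0.396 for each with an estimated correlation). With all genes kept, these medians were 0.13, -0.01 and 0.03 after quantile normalization, and those of B-restricted and CD4 T-restricted genes 0.68 and 0.18 at a pseudocount of 0.1. The lists were defined on these samples, but not on the Th2 libraries. ES-restricted genes were called at a pseudocount of 0.1 (median 0.16, camera adjusted p = 0.00276), with a filter of 5 FPKM (0.03, camera adjusted p = 0.0361) and after median-ratio scaling (0.02, camera adjusted p = 0.0246). At the main setting their camera adjusted p with an estimated correlation was 0.406.

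Changes with TSA ran against those between Th2 cultures and CD4 T cells for genes such as Insig1. The latter changes also carry the file kind and the B and myeloid transcripts of the CD4 T library, so they are not differentiation alone. Across 12367 genes, which are not independent replicates, the covariance of the log2 fold changes was -0.191 (Pearson r = -0.238). It was -0.432 at a pseudocount of 0.1 and -0.125 after quantile normalization. Both comparisons use the untreated Th2 libraries, and unchanged groups sharing them gave a covariance of -0.015 (range -0.019 to -0.013 over 100 simulated draws; r = -0.407), which leaves a difference of -0.176 at the pseudocount of 1, the only one simulated. The simulation had no floor at 0, while genes near 0 in untreated Th2 cultures could hardly fall with TSA. The simulated r was also more negative than the observed one. With 1 untreated library in each comparison, a split chosen after seeing the data, the covariance was -0.197 or -0.146. Of genes that fell in Th2 cultures 617 rose with TSA, where independent lists, which leave out the shared libraries, give 451, and of genes that rose in Th2 cultures 210 fell with TSA, where independent lists give 89.6. In the same direction, 140 rose in both (199.7 for independent lists) and 171 fell in both (202). Unchanged groups sharing the libraries gave 0 calls in either comparison alone in each of 100 simulated draws, which leave out the real effects. Their 0 calls in common were thus fixed in advance and give no value to set against the observed overlaps. Part of the excess in calls may come from the shared libraries.

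Positions of genes always reported, and of Il5, are on GRCm38.p6. Pou5f1 lies on chromosome 17 from 35506032 to 35510777, Cd3e on chromosome 9 from 44998735 to 45009663, and Cd4 on chromosome 6 from 124864693 to 124888247. Gata3 lies on chromosome 2 from 9857078 to 9887953, and Il4 and Il5 on chromosome 11 from 53612460 to 53618665 and from 53720794 to 53725103. Ezh2 lies on chromosome 6 from 47530274 to 47595270, Men1 on chromosome 19 from 6334979 to 6340894, and Kmt2a on chromosome 9 from 44803355 to 44881352. The annotation places F830010H11Rik over Ezh2, Gm39326 over Kmt2a, and 4930412O13Rik and 9230102O04Rik over Gata3, and reads from overlapping genes cannot be told apart without strand.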

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

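Row sums and separate libraries without the replicate block had been the plan, and were run as alternatives once the main method was changed after the files were seen. Row means, separate libraries with the replicate block, the spread pooled from the Th2 files, the filter on the 4 Th2 files, the leaving out of genes at 0 in these files and the split of the untreated libraries were alternative tests chosen only after the result was seen. In the lineage comparisons the counts of genes, 2920, 2947 and 551, stayed within 1.5 times under every alternative run. The size rule uses no spread between libraries, so counting libraries separately left these counts unchanged. Leaving out 1 of 2 near-identical libraries could also change them little. With an estimated correlation no list was called in any comparison, 0 in each (lowest adjusted p 0.22, 0.34, 0.424, 0.63 and 0.755, and 6, 4, 1, 1 and 0 lists at an unadjusted p under 0.05, in the order of the report). This test rests on 2 residual degrees of freedom, so it cannot decide whether the calls hold. For CD4 T against B cells 16 lists lay outside the random range, while camera, a different test, called 7 with separate libraries, 7 with the replicate block added, 8 with the pooled spread, 8 with the replicate block on that spread and 7 with its single prior spread. The share of this drop due to the test was not measured. For Th2 against CD4 T cells fry, which tests lists against no change, called 19 lists, without the ribosome biogenesis and HDAC inhibitor response lists called by camera. Fry, but not camera, called the pluripotency, T cell, cytotoxic, regulatory T, activation, Polycomb, histone deacetylase, germline, imprinted and immediate early lists. Leaving out 1 library gave 3188 to 6790 genes in place of 6795, with 3443 without Th2 replicate 1 and 3188 without replicate 2, where the lone library is assumed to vary like the other groups.

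For TSA the 1729 genes became 771 with no filter, 2833 with the filter on the 4 Th2 files, 2730 without the genes at 0 in all 4, and 6774 with separate libraries or 6927 with the replicate block added. Leaving out 1 library gave 0 to 273 genes (0 without either untreated library, 273 without treated replicate 1, 10 without treated replicate 2) and 7 to 17 lists in place of 12 (7 without untreated replicate 1), and fry called 2 lists, imprinted and quiescence, neither of which camera called. The replicate block with pairs counted once gave 1896 genes, of which 1154 were shared with the 1729, and 2342 with the compared libraries alone; for Th2 against CD4 T cells it gave 8047. With the block over all libraries the interferon, Th2 and T cell lists (camera adjusted p = 0.0501 for each) and the immediate early list (0.141) lost their calls with TSA and the quiescence list gained one (0.0441), and in Th2 against CD4 T cells the activation and immediate early lists gained calls (0.0429 for each). With that block and an estimated correlation the gained calls were lost (camera adjusted p = 0.796 for quiescence and 0.843 for the other lists). That block changed no other list call in these comparisons. Deviations of same-numbered Th2 and treated libraries correlated at 0.577 across genes, so these libraries shared part of their deviation. The main fit has no replicate term, and its p-values for TSA ignore this. Other pairs of groups were at 0.002 to 0.06, but each includes a group whose libraries differed only by sampling. The titles do not say what libraries of 1 experiment number share, and 2 pairs are too few to tell. In the lineage comparisons with each pair counted once, the compared libraries alone gave no test, with no residual degrees of freedom left, and the replicate block was run on the pooled spread.

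ES-restricted genes were called at a pseudocount of 0.1 (median 0.156, camera adjusted p = 0.00276), a filter of 5 FPKM (0.026, camera adjusted p = 0.0361) and median-ratio scaling (0.016, camera adjusted p = 0.0246), against a median of 0.021 and camera adjusted p = 0.163. The B-restricted median of 0.357 lost its call with an estimated correlation (camera adjusted p = 0.406), and the ES-restricted list had the same adjusted p in that test at the main setting. The covariance of -0.191 moved to -0.432 at a pseudocount of 0.1 and -0.125 after quantile normalization. Of 428 results for single genes 229 lost and 9 gained a call under at least 1 alternative, and 3 changed sign in Th2 against CD4 T cells: Mtf2 (0.033, median-ratio scaling), Il1rl1 (0.152, quantile normalization) and Nr4a2 (0.042, quantile normalization). The alternatives include fits without 1 Th2 library, which leave 1 sample in a group, so part of the lost calls reflects fewer samples. The cause of the changed signs was not tested. The unknown depth leaves the precision of low genes open.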

Other observations

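The genes in the next paragraph, and all tests of explanations below, were chosen only after the result was seen.

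TSA-treated Th2 cultures had higher levels of 3 genes of the Bex family, which neurons express. Bex1 rose from 0.88 ± 0.11 to 25.1 ± 8.39 FPKM (SD, n = 2), Bex2 from 0.98 ± 0.37 to 17.1 ± 5.90 and Bex4 from 0.26 ± 0.24 to 9.33 ± 4.12 (limma adjusted p = 0.0298, 0.0336 and 0.0388). The calcium-binding protein genes S100a10 and S100a11 rose from 464 ± 48.4 to 2134 ± 310.5 and from 129 ± 21.9 to 690 ± 175, and Plac8 from 119 ± 1.51 to 822 ± 150.4. Fasn fell from 90.6 ± 1.24 to 22.4 ± 5.66, Fads1 from 25.1 ± 1.07 to 9.32 ± 1.89 and Scd1 from 33.8 ± 7.03 to 9.22 ± 2.19, and Cyp11a1 fell from 470 ± 90.8 to 138 ± 29.9, each with a limma adjusted p of at most 0.0442. Acaca was at 11.5 ± 1.32 and 6.72 ± 2.30 (limma adjusted p = 0.171). No list holding these genes was tested.

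B cell transcripts in the CD4 T library may come from B cells remaining after a sort stated at over 98% purity. Their median share of 6.07% was more than that purity would leave if B and CD4 T cells held equal amounts of RNA. The quartiles of the CD4 T to B level of 20 B list genes lay 1.45-fold apart, as 1 source would give, with Cd79b at 64.2 and 1108 FPKM. Even cross-talk between sequenced libraries is argued against, because pluripotency genes stood at a median of 0.0246% of their ES level. Cells rich in MHC class II other than B cells may add to it. The 5 class II genes stood 4.10 times above the other B list genes, and 12 of 14 myeloid genes with at least 5 FPKM were higher in CD4 T than in B cells, with Lyz2 at 93.2 and 16.7.

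B list genes stood higher in treated Th2 cultures, with both treated above both untreated libraries for 24 of 25 genes; H2-Ab1 was the exception. After quantile normalization the median log2 fold change of the list was 0.96 against 1.36, smaller but still above 0. The list also kept its call (camera adjusted p = 3.42e-06). Camera compares a list with all other genes, where a shift common to all genes largely cancels. The kept call therefore cannot decide whether a scaling difference added to the rise. More B cells left in the treated cultures stay open. The rise was a median of 0.658% of the B library level over all 25 genes, with quartiles 3.52-fold apart. The 1.45-fold above was over the 20 genes outside class II, so these spreads are not directly comparable. Over those 20 genes the rise ran from 0.0391% (Cr2) to 6.3% (Vpreb3) of the B level, and the CD4 T share from 4.71% to 19.2%. Cr2 was near 0 in the cultures, at 0.01 FPKM untreated and 0.10 treated, so its share is uncertain. The state of B cells after days in culture is also unknown. A direct effect of TSA on these genes in T cells was not tested, and the call was lost with an estimated correlation.

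Patl2 stood at 632 FPKM in CD4 T cells and 0.12 ± 0.12 in Th2 cultures. A candidate explanation is that reads of B2m, which lies inside the Patl2 span on chromosome 2 from 122120108 to 122186189, were assigned to Patl2 in the ES, B and CD4 T files. Patl2 was at 33.6%, 31.4% and 31.1% of B2m in these groups, a ratio varying 1.08-fold while B2m varied 30.9-fold, and at 0.00444% in Th2 cultures. No biological explanation was tested.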
